A study of Arabidopsis thaliana with 6 samples.

How the data were processed

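Total RNA of whole seedlings was labelled and hybridised to Affymetrix arrays, per the labels' protocols, from 3 sets each of wild type and gapcp1gapcp2 double mutant seedlings treated with ABA. The growth conditions were 16 h light and 8 h dark at 22 °C and 100 µmol of light per square metre and second. Groups and replicate numbers were taken from the sample titles. One free-text label speaks of embryos, while the source, tissue and protocol labels all name seedlings, and it was not used. The deposited values are probe-set intensities on a linear scale, 1 column per array. The submitters' processing notes name GCOS, the Affymetrix software, and the summarisation, scaling and version are not given in the sources used here. The values include negative ones (3919 over the 6 arrays), so something had been subtracted from the intensities, and what it was is not given. Array medians were similar but not equal (105.8 to 113.0). Control probe sets were not among the rows.

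Names came from the platform's probe table and were updated by gene ID through a RefSeq gene table of the TAIR10.1 assembly. Of 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 were unnamed here. Of those with 1 gene, 13436 matched the RefSeq table. No coordinates are given, because the deposited files name no genome build to set against that of the table.

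Intensities below 0 were raised to 0 and transformed as log2(value + 16), with no further normalization, and the lowest 30% of probe sets by mean over all 6 arrays were left out. The floor at 0 was not part of the plan made before the data were examined, which did not foresee negative values. Differences on this scale understate changes of dim genes. The genotypes were compared with limma (version 3.58.1 in R 4.3.3), lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, using for each gene the probe set with the highest mean, where at least 3 members were measured. A set of 51 lists was fixed before the data were examined. A further 21 lists were written after the probe table had been seen and before any gene was tested. The genes to be named were GAPCP1 and GAPCP2, the 10 highest and 10 lowest of the genes past the threshold with all mutant arrays on one side, up to 4 members per list of the first tier by adjusted p, or the 2 with the largest difference where none passed, and up to 3 members of any other list past the camera threshold. No gene passed, so 35 genes were named, by list. Genes named outside this rule are said to have been chosen after their values were seen.

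The fit was tested on simulated data with 200 of 15922 probe sets changed in each of 10 runs. Of simulated 4-fold changes 97.0% were recovered, of 2-fold 74.0% and of 1.5-fold 27.4%, with a mean of 9.40 false calls per run. The same folds were also added to the measured arrays, on the log2 scale used for the fit and as factors on the deposited intensities. Alternatives were no filter, a filter of 50%, quantile normalization, centring on the median or 75th percentile, pseudocounts of 1 and 64, eBayes without trend or robust, array weights, the replicate number as a block, and leaving out each array. For the lists they were an estimated correlation and all probe sets of a gene averaged. A generalized log2 without the floor was added after seeing the data, as was an estimated correlation for the lists that passed with 1 array left out. Figures were drawn with matplotlib 3.10.9.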

Results

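Transcript levels were measured on Affymetrix arrays in whole 15-day-old Arabidopsis thaliana seedlings of the Col-0 ecotype, in wild type and in the gapcp1gapcp2 double mutant. GAPCP1 and GAPCP2 encode plastidial isoforms of the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase. All seedlings had received 0.75 µM abscisic acid (ABA), a plant hormone of stress responses and seed dormancy, for 8 days. Each genotype had 3 arrays, titled as biological replicates, and all 6 arrays came from treated plants, so the response to ABA itself was not compared. Each array gave 22746 probe-set intensities, with array medians between 105.8 and 113.0 and between 395 and 785 values below 0. The number of arrays limits the precision of every value.

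The comparison asks which transcripts differ between the double mutant and wild type when both are grown with ABA. No probe set passed the threshold: of the 15922 tested with limma, 0 were higher and 0 were lower in the mutant at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 271 probe sets, 177 higher and 94 lower in the mutant, where uniform p-values would give 796. The smallest adjusted p was 1.00. All 3 mutant arrays lay on one side of all 3 wild type arrays for 1001 probe sets (6.29%, where chance gives 10%), and 3 of these differed by at least 1 on the log2 scale. For 15516 probe sets the 95% interval of the log2 difference lay within -1 to 1. Known 4-fold changes added to the mutant arrays on the log2(value + 16) scale were recovered in 97.4% of cases, 2-fold changes in 74.2% and 1.5-fold changes in 24.2%. Applied as factors to the intensities themselves, they were recovered in 93.0%, 63.8% and 18.6%. In both cases 200 probe sets were changed at once, which eases the Benjamini-Hochberg adjustment. These shares therefore overstate the recovery of a few changed genes. The probe sets of GAPCP1 and GAPCP2 are unnamed in the probe table used here, so the targeted genes could not be analysed by name and did not check the genotype labels. Unnamed probe sets above the filter were among the 15922 tested, of which 0 passed.

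No measured gene of carbon metabolism passed the test. Of the 7 measured genes of cytosolic glycolysis, 0 passed the test, over all probe sets or adjusted over the list alone, and camera gave the list an adjusted p of 0.832. Their mean log2 difference was -0.0092 and their median 0.015. AT5G08570, a pyruvate kinase gene, had an intensity of 967 ± 91.1 in wild type and 866 ± 48.1 in the mutant (SD, n = 3), a log2 difference of -0.15 ± 0.10 (SE). AT5G42740, for cytosolic phosphoglucose isomerase, had 341 ± 5.44 and 355 ± 0.714 (SD, n = 3). None of the 5 measured genes of starch metabolism passed (camera adjusted p = 0.832). APL4, a subunit of ADP-glucose pyrophosphorylase, had a log2 difference of 0.11 ± 0.21 (SE), and SBE2.2, a starch branching enzyme, 0.059 ± 0.12 (SE). The sugar transporter gene SWEET11 had 0.046 ± 0.088 and the invertase gene AT1G62660 -0.023 ± 0.41. Among genes known to rise in sugar starvation, IVD had 0.14 ± 0.19 and MCCA 0.042 ± 0.10.

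Amino acid and lipid genes had few probe sets named in the probe table used here, of which 0 passed. AT1G32470, for the H protein of the photorespiratory glycine decarboxylase, had an intensity of 4079 ± 417 in wild type and 4106 ± 166 in the mutant (SD, n = 3). AT1G11860, for its T protein, had 4012 ± 430 and 4012 ± 426 (SD, n = 3). AT2G04400, of tryptophan synthesis, had a log2 difference of -0.073 ± 0.10 (SE), and AT5G38710, a proline dehydrogenase gene, -0.067 ± 0.30. The acyl carrier protein thioesterase genes FaTA and FATB had -0.092 ± 0.15 and 0.057 ± 0.096.

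No measured gene of the ABA response passed either. Of 5 measured ABA-responsive genes 0 passed, 4 were fitted above 0 and 1 below, and camera gave an adjusted p of 0.832. Arrays of one genotype differed in this list, which limits the comparison. Relative to the list mean over arrays, wild type 2 was at -0.26 and wild type 1 at 0.26, mutant 1 at -0.17 and mutant 2 at 0.17. COR47, LTI30 and LEA4-5 ran this way, and COR15B did so in wild type only. COR15A ran the opposite way, with 1749 in wild type 2 and 1654 in mutant 1. It had 1073 in wild type 1 and 1093 in mutant 2. The late embryogenesis abundant gene LEA4-5 had an intensity of 78.7 ± 42.6 in wild type and 79.3 ± 22.3 in the mutant, and the cold- and ABA-induced gene COR15A 1365 ± 347 and 1302 ± 307 (SD, n = 3).

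Photosynthesis genes gave no call. None of the 6 measured genes of the photosystems and electron transport passed (camera adjusted p = 0.832, mean log2 difference -0.0061, median 0.0019). The photosystem I gene PSAE-1 had a log2 difference of -0.066 ± 0.064 (SE) and the antenna gene LHCB4.1 0.034 ± 0.068. Of 4 Calvin-Benson cycle genes 0 passed (camera adjusted p = 0.832). The phosphoglycerate kinase gene AT1G56190 had 0.074 ± 0.11 and SBPASE, for sedoheptulose-bisphosphatase, -0.034 ± 0.086.

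Markers of cell types and organs gave no call. The root hair expansin genes EXPA18 and EXPA7 had log2 differences of -0.12 ± 0.40 and -0.063 ± 0.30 (SE). The root ER body genes PYK10 and NAI2 had -0.060 ± 0.14 and 0.044 ± 0.16, and the guard cell regulator FMA -0.072 ± 0.14. The cell cycle kinase genes AUR2 and AUR1 had 0.22 ± 0.16 and 0.061 ± 0.13, and the 3 measured cell cycle genes had a camera adjusted p of 0.673.

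Stress, pigment and timing genes included one member below 0.05 within its own list. WRKY53, a transcription factor gene of defence and senescence, had an intensity of 148 ± 9.87 in wild type and 188 ± 15.7 in the mutant (SD, n = 3), a log2 difference of 0.31 ± 0.11 (SE). Its limma p was 0.0213, 0.0425 adjusted over the list alone and 1.00 adjusted over all probe sets. Such a member occurred in 1 of the 33 fixed lists with a measured gene. The other member of that handling-response list, STZ, had 0.076 ± 0.22. The defence genes SAG101 and PDF1.2 had log2 differences of -0.22 ± 0.20 and -0.13 ± 0.18. In the flavonoid list 0 of 5 passed (camera adjusted p = 0.673), and DFR, of anthocyanin synthesis, had -0.23 ± 0.15 and UGT78D1 -0.20 ± 0.15. The clock genes GI and COR27 had 0.047 ± 0.11 and -0.033 ± 0.25.

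Across the 51 gene lists fixed before the data were examined, 85 of 759 listed members were tested, in 33 lists. Most of the others had no probe set with 1 named gene. Of those tested 0 passed, with log2 differences from -0.40 to 0.31. Of the 12 lists with at least 3 measured members, camera placed 0 past an adjusted p of 0.05, with the preset or the estimated correlation. The smallest adjusted p was 0.673, and 0.901 with an estimated correlation. The remaining tested lists were ferritins and antioxidant enzymes (mean log2 difference 0.10, adjusted p = 0.673), auxin response (0.089, adjusted p = 0.673), aliphatic glucosinolates (0.044, adjusted p = 0.832), alternative respiration (-0.094, adjusted p = 0.832) and wall loosening (0.064, adjusted p = 0.832). Another 21 lists had 1 or 2 members that passed the filter and no list test, and 18 had none. Of these 18, 15 had no named probe set at all. ABA receptors, PP2C phosphatases, plastid glycolysis and the phosphorylated serine pathway were among those not analysed here.

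**Figure D1:**
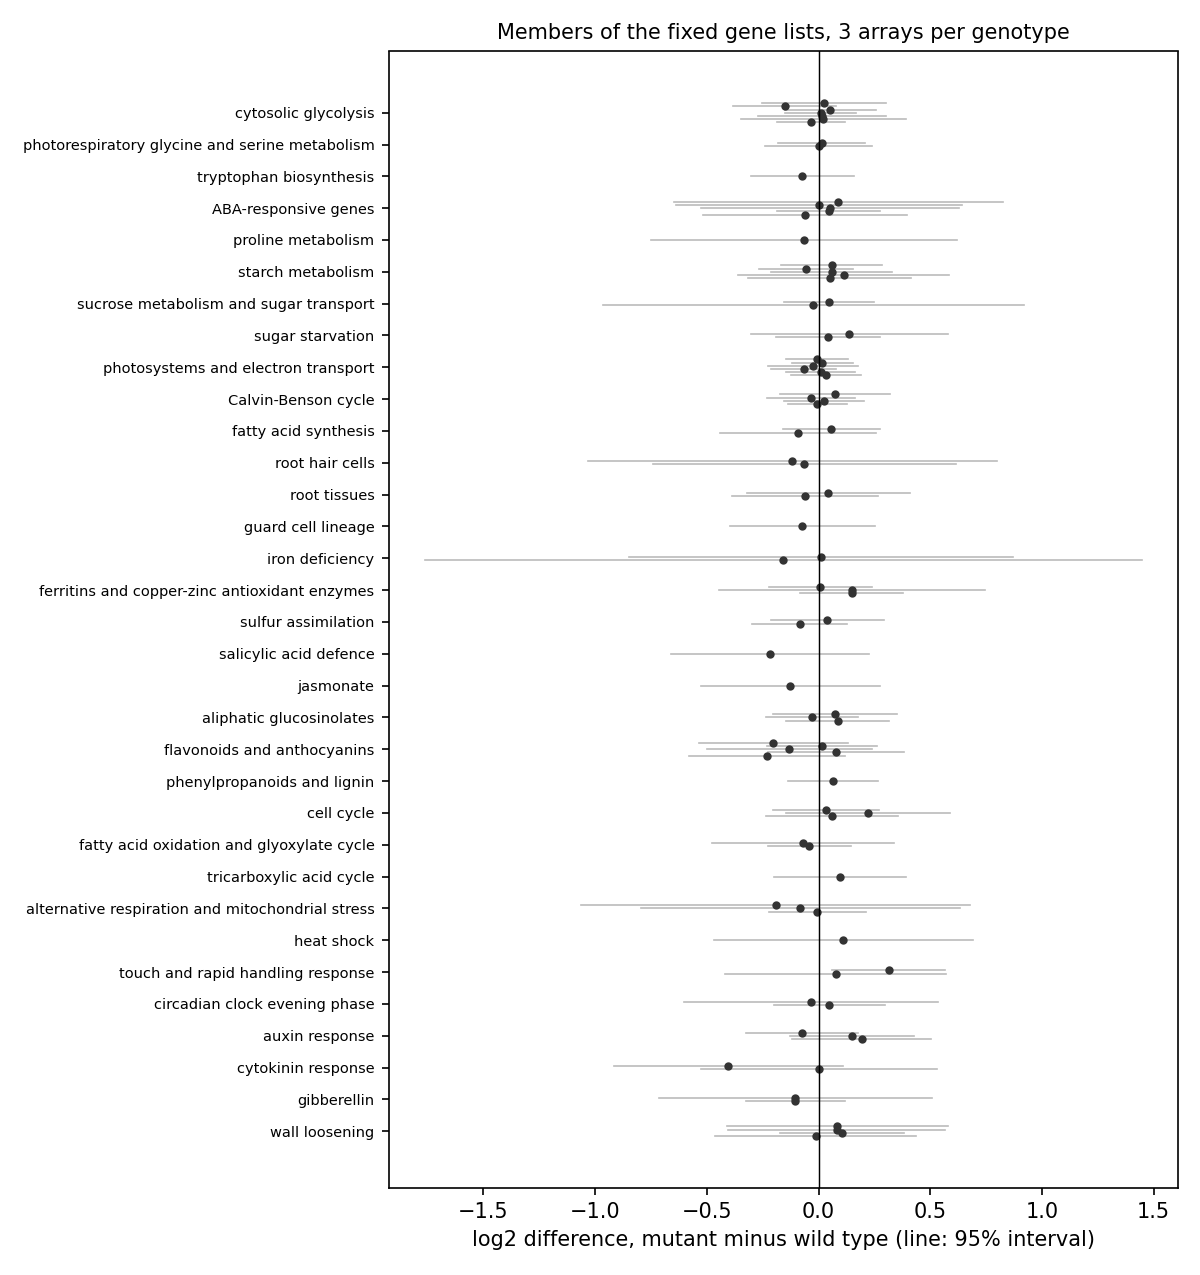
Log2 difference between mutant and wild type for each measured member of the fixed gene lists (horizontal axis, log2 units), by list (vertical axis). Points are limma estimates from 3 arrays per genotype and lines their 95% intervals. The points lie between -0.40 and 0.31.

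Arrays did not group by genotype. The first principal component held 43.4% of the variance between arrays and the second 21.0%. Of these components 0.050% and 4.29% lay between the genotypes. The third held 16.0% of the variance, of which 35.1% lay between the genotypes, and there wild type 3 lay farthest from 0 (-21.0). Of the whole variance between arrays, 13.3% lay between the genotypes, where an arbitrary split gives 20.0%. The SD of the log2 difference between a pair of arrays averaged 0.325 over the 6 pairs of one genotype and 0.301 over the 9 pairs of different genotypes. The closest pairs were wild type 1 with mutant 3 and wild type 2 with mutant 1, both at 0.240.

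**Figure D2:**
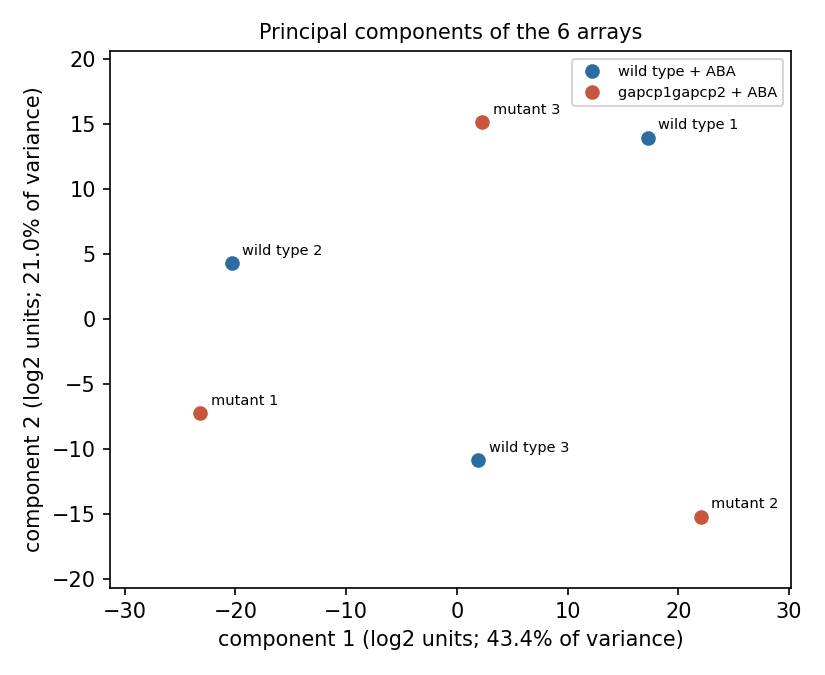
Scores of the 6 arrays on the first (horizontal axis) and second (vertical axis) principal component of the log2 intensities of the tested probe sets, coloured by genotype. Wild type 1 and mutant 2 lie at one end of the first component (17.2 and 22.0), wild type 2 and mutant 1 at the other (-20.3 and -23.2).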

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

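The generalized log2, and the estimated correlation with 1 array left out, were chosen after seeing the data, and the other alternatives before. Under all 18 alternatives limma again placed 0 probe sets past the threshold, higher or lower, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 the count of 271 became 619 without the filter and 115 with the lowest 50% left out, which changes how many probe sets are tested. The generalized log2 gave 271. With the replicate number as a block it was 136, and 0 passed. Same-numbered arrays did not deviate together (correlations across probe sets of -0.59, -0.49 and -0.13 for replicates 1, 2 and 3), and 0 of the 6 arrays correlated best with its own number. The numbers were therefore not treated as pairs. Wild type 2 with mutant 1 gave 0.60 and wild type 1 with mutant 2 gave 0.39, so a pairing across numbers is not excluded. The protocol label says that the sets of both genotypes grew together, without tying a set to a number. The block changed no call, but a block on the number cannot account for growth sets that cross the numbers. For the fixed lists camera placed 0 past the threshold under all alternatives run. For the lists written later the count was 0, with a range of 0 to 2 when 1 array was left out. Without wild type replicate 1, plastid-encoded photosynthesis genes and plastid-encoded gene expression machinery passed (adjusted p = 2.12e-05 and 2.13e-05), but not with an estimated correlation (adjusted p = 0.985 for both). Wild type 1 was the lowest array for both lists. Without wild type replicate 2, ER body and jacalin lectins passed (adjusted p = 0.0386), but not with an estimated correlation (adjusted p = 0.949). The cause was not tested.

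Directions were not stable. The sign of the named genes' differences turned in 46 of 210 values with 1 array left out, in 25 of 35 genes, and in 1 of 413 values under the other alternatives, AT1G11860 with quantile normalization (-0.011). No named gene passed under any of these. Of the 10 genes whose sign did not turn, 8 moved by over 1.5 times with 1 array left out, namely AT5G08570 (-0.23 to -0.094), AT2G04400 (-0.14 to -0.014), PSAE-1 (-0.10 to -0.023), FATB (0.00070 to 0.096), SAG101 (-0.38 to -0.045), DFR (-0.38 to -0.12), UGT78D1 (-0.33 to -0.11) and AUR2 (0.13 to 0.37), as did all 8 lists that did not turn, among them flavonoids (-0.15 to -0.018) and auxin response (0.018 to 0.13). With 1 array left out the log2 differences ranged over AT1G32470 (-0.038 to 0.095), AT1G11860 (-0.079 to 0.082), LEA4-5 (-0.27 to 0.42), COR15A (-0.25 to 0.13), AT5G38710 (-0.29 to 0.20), APL4 (-0.020 to 0.24), SBE2.2 (-0.020 to 0.16), SWEET11 (-0.014 to 0.10), AT1G62660 (-0.43 to 0.36), IVD (-0.089 to 0.33), MCCA (-0.027 to 0.10), LHCB4.1 (-0.0047 to 0.096), AT1G56190 (-0.025 to 0.14), SBPASE (-0.099 to 0.025), FaTA (-0.23 to 0.039), EXPA18 (-0.59 to 0.27), EXPA7 (-0.23 to 0.24), PYK10 (-0.16 to 0.085), NAI2 (-0.094 to 0.22), FMA (-0.18 to 0.034), PDF1.2 (-0.31 to 0.025), AUR1 (-0.021 to 0.15), STZ (-0.049 to 0.29), GI (-0.043 to 0.10), COR27 (-0.27 to 0.20). The camera direction turned with 1 array left out for 7 of the 12 fixed and 18 of the 21 later lists, whose mean log2 differences then ranged over cytosolic glycolysis (-0.056 to 0.017), ABA-responsive genes (-0.099 to 0.16), starch metabolism (-0.024 to 0.11), photosystems and electron transport (-0.035 to 0.033), Calvin-Benson cycle (-0.036 to 0.054), alternative respiration and mitochondrial stress (-0.30 to 0.14), wall loosening (-0.047 to 0.17), plastid-encoded photosynthesis genes (-0.11 to 0.12), plastid-encoded NDH complex (-0.094 to 0.12), plastid-encoded gene expression machinery (-0.14 to 0.060), nuclear photosynthesis genes (-0.041 to 0.042), tetrapyrrole and chlorophyll synthesis (-0.017 to 0.016), dehydration and ABA-responsive genes (-0.010 to 0.086), ER body and jacalin lectins (-0.14 to 0.033), branched-chain amino acid and electron transfer flavoprotein catabolism (-0.048 to 0.056), tau class glutathione transferases (-0.081 to 0.013), CYP71B cytochromes P450 (-0.15 to -0.011), SWEET sugar transporters (-0.011 to 0.13), expansins and xyloglucan endotransglucosylases (-0.024 to 0.082), ATG8 autophagy proteins (-0.13 to 0.049), immune and wound-induced regulators (-0.049 to 0.010), plant defensins and thionins (-0.086 to 0.11), tubulins and actins (-0.037 to 0.061), histones H2B (-0.038 to 0.045), tricarboxylic acid cycle and ATP citrate lyase (-0.079 to 0.065). Otherwise it turned for 5 later lists. Without the filter these were branched-chain amino acid catabolism (mean 0.016), expansins (0.0054), histones H2B (-0.0032) and the tricarboxylic acid cycle (0.00068). With quantile normalization they were histones H2B (-0.011) and the tricarboxylic acid cycle (-0.027), and with the replicate block plant defensins (0.0089). Camera sets a list against the other genes, so its direction can turn while the mean does not. The mean was the same as in the main fit for plant defensins with the block. That also held for branched-chain catabolism and histones H2B without the filter. CYP71B kept a mean below 0 with each array left out. The cause of the other turns was not tested. Signals near the background limit the dim genes, since between 1.74% and 3.45% of values per array were below 0.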

Other observations

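Of the tests below, those of other splits of the arrays, array scaling, exchanged labels and 1.5-fold changes were chosen only after the result was seen. The criteria for 4-fold changes and root peroxidases were set after the patterns they bear on had been seen, including the counts and the splits, but before the recovered share and the peroxidases' values were computed.

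Gene groups outside the report also held no call between the genotypes. In the 21 lists written after the probe table had been seen, 247 genes were tested with limma, 0 passed and 9 had an unadjusted p under 0.05. Camera placed 0 of the 21 lists past an adjusted p of 0.05, and 1 had an unadjusted p under 0.05. That list was the plastid-encoded gene expression machinery, with 14 of 19 members fitted below 0, a mean log2 difference of -0.049 and an adjusted p of 0.214 (adjusted p = 0.981 with an estimated correlation). NAI1, a regulator of ER body formation chosen after its values were seen, had an intensity of 209 ± 10.1 in wild type and 159 ± 6.06 in the mutant (SD, n = 3), with a limma p of 0.0427 adjusted over the list alone and 1.00 over all probe sets. The mean, median and test differed in sign for some lists. Plastid-encoded photosynthesis genes had a mean of 0.015 and a median of -0.019, and the NDH complex 0.013 and -0.014, both tested as lower. The smallest unadjusted limma p of all probe sets was 0.000285, for UCL1, also chosen after its values were seen, at 112 ± 27.0 in wild type and 224 ± 11.3 in the mutant (SD, n = 3).

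Several gene groups differed between individual arrays by more than random genes did, whatever the genotype. Each of 46 lists was set by its SD between arrays against 10000 random lists matched on mean expression, and 11 lay in the top 2.5%, where 1.2 would be expected. Random lists hold unrelated genes, so any set of genes that vary together exceeds them more easily. The percentile ran from 3.16, for tetrapyrrole synthesis, to 100 for 3 lists, which were iron deficiency (2 measured genes), plastid-encoded photosynthesis genes and the plastid-encoded gene expression machinery. The fixed list of ABA-responsive genes lay at percentile 98.6. The iron deficiency regulators BHLH101 and PYE, both of that fixed list but chosen for mention after their values were seen, had their highest intensities in wild type 2 (778 and 243) and mutant 1 (723 and 235), with highest over lowest intensity of 6.70 and 2.92. AT1G47400, in no fixed list and also chosen after its values were seen, had intensities of 217, 1428 and 697 in wild type 1, 2 and 3 and 1386, 161 and 796 in mutant 1, 2 and 3, a ratio of 8.88. The plastid-encoded photosynthesis genes had a list SD of 0.164 between arrays, against a median of 0.0393 for random lists. Relative to its mean over arrays, this list was lowest in wild type 1 (-0.26) and highest in wild type 2 (0.20), as was the plastid-encoded gene expression machinery (-0.16 and 0.24).

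The resemblance of arrays across genotypes was weighed against 3 explanations. Array scaling was argued against only as the source of the counts at an unadjusted p under 0.05. After quantile normalization the genotype split still had 284 such probe sets, and the highest other split 2596. The resemblance between arrays was not computed again after that normalization, so for the resemblance itself scaling was not tested. An unequal share of root tissue between samples may contribute but stays open, since only 1 of the 2 criteria set for it was met. The mean projection of 9 root peroxidases not seen before lay at percentile 100 of 10000 random lists. However, 7 of the 9 (77.8%, where 47.4% of all genes did and at least 90% was required) lay on the side of the 4 seen ones on the first component. Random lists hold unrelated genes, so the percentile cannot tell a share of root tissue from joint regulation of the peroxidases. The iron deficiency list (2 measured genes) ran the opposite way over the same arrays. Relative to its mean over arrays it was low in wild type 1 and mutant 2 (-0.96 and -1.03) and high in wild type 2 and mutant 1 (0.95 and 0.88). The fixed root tissue genes and the mean of the fixed root hair list were also lowest in wild type 2 and mutant 1 and highest in wild type 1 and mutant 2 (percentiles 96.5 and 99.6, with PYK10 at 4383 and 4073 against 6109 and 5514), although EXPA7 alone was lower in wild type 3 than in wild type 2. Leaf functions were mixed. Relative to its mean over arrays the Calvin-Benson list was lower in wild type 1 and mutant 2 (-0.065 and -0.071) than in wild type 2 and mutant 1 (0.068 and 0.11), at percentile 63.8. So were the later lists of nuclear photosynthesis genes (-0.014 and -0.072 against 0.093 and 0.063, percentile 97.4) and plastid-encoded photosynthesis genes (-0.26 and -0.13 against 0.20 and 0.042, percentile 100). The photosystem list followed no such pattern (0.081 and 0.0024 against -0.016 and 0.0098, percentile 30.1), nor did tetrapyrrole synthesis (0.0013 and 0.00091 against 0.023 and -0.034, percentile 3.16). Exchanged genotype labels also stay open, since the mutated genes could not be identified among the probe sets. In the genotype split 3 probe sets were separated by at least 2-fold, and 69 in the highest other split. Growth sets shared by both genotypes, of which the protocol label speaks, were not tested and stay open too. No label ties an array to a set.

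The absence of calls was set against the number of arrays. Of 4-fold changes added to the mutant arrays on the log2 scale 97.4% were recovered, and 93.0% when applied to the intensities. The changes were added to the arrays labelled as mutant, so these shares hold only if the genotype labels are right. On that condition they argue against many changes of this size having been missed among the tested probe sets. They do not argue against a few, since 200 changes were added at once, which eases the adjustment. Of 1.5-fold changes 24.2% and 18.6% were recovered, so small differences may have been missed. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05, and where the real count is 0 all 10 splits give as many by construction, which decides nothing. The real and the highest other count past the adjusted threshold were 0 and 0 for probe sets, 0 and 0 for fixed lists, and 0 and 6 for the lists written later, and 6 of the 10 splits called at least 1 of the later lists. At an unadjusted p under 0.05, 8 of the 10 splits, counting the real split itself, gave at least the real 271 probe sets. The highest other splits each exchanged arrays of the same number between the genotypes. They were wild type 1 with mutant 1 (2424), wild type 2 with mutant 2 (2416) and wild type 3 with mutant 3 (1006). The next highest split gave 676. This order was seen afterwards, and its cause was not tested. The highest count, several times the real one, points to a structure of the samples. However, no reference distribution was computed for the highest of the other splits.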
